A study of Caenorhabditis elegans with 3 samples.

How the data were processed

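RNA from adult Caenorhabditis elegans hermaphrodites (a nematode worm; TP09 is the submitters' unexplained sample code) was hybridised on 3 two-colour arrays. Each array held 1 RNA prep of the adults in channel 2 and a wild-type mixed reference RNA in channel 1, per the labels. The 3 preps form 1 group of 3 replicates, numbered by prep as the labels give them. The labels do not say whether the preps came from separate cultures, so p-values measure the spread between these preps, which may be technical.

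The deposited table holds 1 log2 ratio per probe and array for 20000 probes. That the scale is log2 was worked out from the values: all of the 58013 values within 2 of 0 were the log2 of a ratio with 3 decimals (100%, to within 0.005 thousandths of a ratio), against 0.974% read as natural logs and 1.08% read as log10. The array means lay between -0.006 and -0.003 and the medians at 0.06, 0.00 and 0.02 for replicates 1, 2 and 3, so the deposited log2 values lay near 0 on average. Whether and how the authors centred them, the dyes, the scanner, the background treatment and any spot filter are not given in the sources used here. Values were missing for 101, 193 and 156 probes. Spot intensities were not used here, so no probe could be called above or below background, and the precision rests on the number of arrays.

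The direction of the ratio is also not stated. Channel 2 over channel 1, adult over reference, was taken as likely, because the labels put the adult prep in channel 2 and name it first in the comparison. A check by 3 gene lists was set for it in advance. With the sign turned, every higher value in the text would be a lower one.

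Probes were named through GEO's platform annotation of the array: 15655 probes had 1 gene symbol, 198 had several and 4147 had none. Of those with 1 symbol, 15569 matched a gene of the WBcel235 RefSeq gene table, and no symbol changed. No genome position was used, since the build behind the probes is not given in the sources used here. Each array was centred on its own median over all probes, probes of a gene were averaged, and the 15092 genes with a value on all 3 arrays were tested. Of these, 466 genes had over 1 probe. Among 426 genes with at least 2 complete probes, the median range between probes of a gene was 0.21 on the log2 scale, and 10 genes had probes over 1 apart.

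The mean log2 ratio of each gene was tested against 0 with limma 3.58.1 (lmFit with an intercept, then eBayes) in R 4.3.3, with Benjamini-Hochberg adjustment and a threshold of 0.05. The fit had 2 residual degrees of freedom and a prior of 5.3. The test leaves out the spread of the reference RNA itself. Folds are relative to the median probe, and total RNA per worm was not measured. The 23 gene lists were compared with all other genes by limma's camera with a preset correlation of 0.01, adjusted over the lists; camera with an estimated correlation and fry were run beside it. Counts of list members past the threshold are given over all genes tested and adjusted over the list alone.

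On simulated data with the spread of these 15092 genes and 200 changed genes, the adult against reference test recovered 98% of genes changed by 1 and 33% of those changed by 0.5 on the log2 scale, with 26 false calls among 157, a larger share than the threshold of 0.05 aims at. Both rates depend on how many genes change. In the data 6698 genes passed, so the rates do not carry over to them. A simulated list shifted by 0.5 had an adjusted p of 2.97e-39 by camera with the preset correlation and 0.268 with an estimated one, and none of the 22 other lists was called (count 0). The simulated genes were independent of one another. The simulation therefore does not test the preset correlation on lists of correlated genes, such as the major sperm proteins (estimated correlation 0.74).

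The comparison, the lists, the named genes and most alternatives were fixed before the data were examined. The named genes were the 10 with the largest mean ratio each way among those past the threshold with 1 sign on all 3 arrays, the 2 members of each list with the largest absolute ratio, and every measured yolk protein gene. Other genes that are named were chosen after their values were seen. Alternatives were the values as deposited, scale and quantile normalization, genes with a value on at least 2 arrays, probes tested singly, a robust prior, array weights, limma's treat against a 1.5-fold change, rank-based camera, and leaving out each replicate. Centring by runs of rows or by their 4 repeating positions, testing of unnamed probes, and the list tests after scaling were added after seeing the data. Left out of the tests were the probes with no symbol or several symbols, which the closing section counts.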

Results

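Transcript levels in adult hermaphrodites were compared with those in a wild-type mixed reference RNA on 3 two-colour arrays, each with a separate adult prep. The labels do not state the genotype of the adults, so strain as well as stage and tissue can enter each difference. Values were present for 19899, 19807 and 19844 of the 20000 probes on replicates 1, 2 and 3. After centring and averaging of probes, 15092 named genes had a value on all 3 arrays, and the median SD of a gene's log2 ratio over the 3 arrays was 0.21. Values are log2 ratios of adult over reference, with the SD over n = 3 arrays. The number of arrays limits the precision.

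The direction of the ratio is not stated in the labels, and adult over reference was taken as likely; with the opposite direction all signs turn. The check set for it met its predicted sign on all arrays for 2 of its 3 lists. Genes of oocytes and the eggshell had medians of 1.49, 1.24 and 1.40 on replicates 1 to 3, and genes of moulting and the larval epidermis had medians of -0.63, -0.55 and -0.65. The yolk protein list, with 3 genes measured, had medians of -0.18, 0.31 and 0.39, so its sign differed between arrays. The adult-specific collagen gene col-19, chosen after its value was seen, stood at 2.12 ± 0.15 (adjusted p = 4.55e-05, limma). Adult over reference was kept as the likely direction.

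Oocyte, P granule, meiosis, cell division and proteasome genes were higher in adults than in the mixed reference by camera with a preset correlation. By the same test, neuron, larval epidermis and major sperm protein genes were lower. None of these lists was called with an estimated correlation (adjusted p = 0.613 for major sperm proteins and adjusted p = 0.243 for each of the others). That test rests on 2 residual degrees of freedom. It also missed a list shifted by 0.5 in simulated data with independent genes (adjusted p = 0.268), so the lack of a call by it does not decide against a shift. The simulation does not bear on the major sperm proteins, whose genes had an estimated correlation of 0.74. That list was not called by fry either (adjusted p = 0.0766). The list medians reached 1.37, or 2.59-fold, for genes of P granules, and -0.81, or 1.76-fold lower, for neuron genes. Of the 15092 genes, 6698 (44.4%) differed between adult and reference by limma at an adjusted p under 0.05. The adult level was higher for 3152 genes (20.9%) and lower for 3546 (23.5%), and 6688 of the 6698 had the same sign on all 3 arrays. Among these named genes the lower side reached further against this mixed reference, whose make-up also sets the size of each ratio. Probes without a symbol reached further on the higher side, with extremes of 5.47 and -3.72. Among the named genes, over 2-fold differences were called for 986 higher and 1353 lower genes. Over 4-fold differences were called for 48 higher and 303 lower named genes. Centring on the median makes the numbers of higher and lower genes similar by construction. Tested against a 1.5-fold change, 912 genes were higher and 1164 lower.

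Among genes named by a single symbol, the highest ratio was that of irg-5 (F35E12.5), an infection response gene, at 3.82 ± 0.20, a 14.1-fold higher level in adults (adjusted p = 1.48e-05); 2 probes without a symbol lay above it, at 5.47 and 4.78. It was followed by the cuticle collagen gene col-101 (K02D7.3) at 3.49 ± 0.14 and by pud-2.1 (F15E11.1) at 3.19 ± 0.59. The related gene pud-4 (F15E11.12) stood at 3.10 ± 0.97. Close copies such as these can share signal on an array, so their separate values are uncertain. The glucuronosyltransferase gene ugt-22 (C08F11.8) stood at 3.10 ± 0.46, the acyl-CoA dehydrogenase gene acdh-1 (C55B7.4) at 3.08 ± 1.00, and the collagen gene col-8 (F11H8.3) at 2.95 ± 0.21. The uncharacterised genes H11L12.1, C27C7.1 and T16G12.3 stood at 3.12 ± 0.64, 3.08 ± 0.37 and 3.08 ± 0.41. The adjusted p of each of these genes was 0.000307 or lower.

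Among the same genes, the lowest ratio was that of the alcohol dehydrogenase gene adh-1 (K12G11.3), at -5.62 ± 0.40, a 49.3-fold lower level in adults (adjusted p = 9.73e-06). The acyl-CoA synthetase gene acs-2 (F28F8.2), which is induced by fasting, was 31.1-fold lower, at -4.96 ± 0.45. The C-type lectin gene clec-60 (ZK666.6) stood at -4.82 ± 0.70, and C08E3.13 at -4.82 ± 0.16. Collagen genes were again among the extremes, with col-36 (C27H5.5) at -4.75 ± 0.61 and rol-8 (ZK1290.3) at -4.65 ± 0.59. The secreted protein gene scl-2 (F49E11.10) stood at -4.42 ± 0.23, the fatty acid desaturase gene fat-3 (W08D2.4) at -4.41 ± 0.16, pals-39 (C54D10.7) at -4.40 ± 0.83, and the small heat shock protein gene hsp-12.6 (F38E11.2) at -4.29 ± 0.07. The adjusted p of each of these genes was 5.54e-05 or lower.

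**Figure D1:**
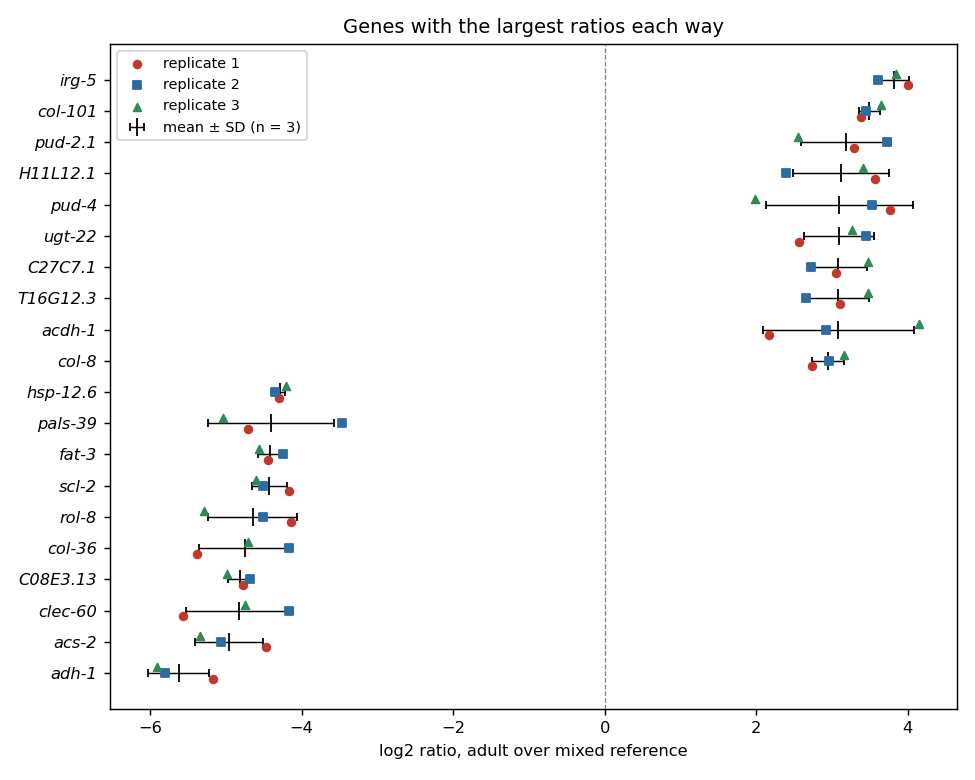
Log2 ratio of adult over mixed reference for the 10 genes with the largest mean ratio each way; coloured symbols are the 3 replicates and black bars are the mean ± SD (n = 3). The higher genes reach 3.82 (irg-5) and the lower genes -5.62 (adh-1), and all 3 replicates of each gene lie on one side of 0.

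Genes of oocytes and the eggshell, of P granules and of meiosis were higher in adults as groups. Of 33 measured oocyte and eggshell genes, 30 were higher, 2 were lower and 1 did not pass, with a median of 1.33, or 2.52-fold. The yolk receptor gene rme-2 stood at 2.30 ± 0.42 and the eggshell gene cbd-1 at 2.21 ± 0.11. The 2 lower members were egg-1 at -0.51 and moe-3 at -0.52. Of 31 genes of P granules (RNA-protein bodies of germ cells) and germline RNA control, 29 were higher and 2 did not pass, with a median of 1.37. The P granule helicase genes glh-1 and glh-2 stood at 2.50 ± 0.15 and 2.40 ± 0.05; they are similar in sequence and can share signal. Of 32 meiosis genes, 28 were higher and 4 did not pass, with a median of 0.93, led by xnd-1 at 1.56 ± 0.04 and by the helicase gene him-6, which was 2.82-fold higher. Adjusted over the list alone, the higher members numbered 30, 29 and 29. By camera, the adjusted p was 4.71e-13 for the oocyte, 3.96e-14 for the P granule and 1.33e-11 for the meiosis list; each had an adjusted p = 0.243 with an estimated correlation.

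Genes of cell division and protein turnover were also higher. Of 52 DNA replication and cell division genes, 45 were higher and 7 did not pass, with a median of 1.15, or 2.22-fold (camera adjusted p = 7.6e-16, and adjusted p = 0.243 with an estimated correlation). The kinesin gene klp-7 stood at 1.88 ± 0.31 and the replicative helicase gene mcm-2 at 1.83 ± 0.42. Of 31 proteasome genes, 29 were higher and 2 did not pass, with a median of 0.84 (camera adjusted p = 7.14e-12, and adjusted p = 0.243 with an estimated correlation), led by the regulatory particle genes rpn-1 at 1.75 ± 0.16 and rpn-2 at 1.47 ± 0.20. Adjusted over the list alone, 45 and 30 members were higher.

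Most ribosomal protein genes did not pass the test. Of 63 measured, 15 were higher, 4 were lower and 44 did not pass, with a median of 0.25; adjusted over the list alone, 8 were higher and 3 lower. The list was called by camera (adjusted p = 0.00788), with an adjusted p = 0.737 with an estimated correlation and 0.167 by fry. Its members with the highest ratios were rpl-23A.2 at 1.07 ± 0.18 and rpl-11.1 at 1.07 ± 0.21. Of 55 core histone genes, 2 were higher, 15 were lower and 38 did not pass (camera adjusted p = 0.215); adjusted over the list alone, 1 was higher and 15 lower. The histone genes his-71 and his-1 stood at -1.20 ± 0.23 and -1.01 ± 0.13. Histone genes have near-identical copies, and which copy a probe reported is uncertain.

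Major sperm protein genes, which encode the cytoskeletal protein of nematode sperm, were lower in adults. Of 30 measured, 26 were lower and 4 did not pass, with a median of -0.79, or 1.73-fold lower; adjusted over the list alone, 27 were lower. Examples are msp-51 at -1.28 ± 0.43 and msp-59 at -1.27 ± 0.43. These genes are close copies of one another, so the 30 values are not separate measurements. The medians were -0.84, -1.18 and -0.43 on replicates 1 to 3. The camera adjusted p was 1.38e-07, with an adjusted p = 0.613 with an estimated correlation and 0.0766 by fry. Of 50 other sperm genes, 4 were higher, 13 were lower and 33 did not pass, over all genes and over the list alone (camera adjusted p = 0.125; 0.0399 without replicate 3). The members with the lowest ratios were nspc-20 at -2.95 ± 0.68 and nspc-9 at -2.11 ± 0.44, of a nematode-specific peptide family. Among the lower members were also sss-1 at -1.22 and spe-27 at -1.32, while spe-39 stood at 1.22 and spe-44 at 0.96.

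Genes of the larval epidermis were lower, and collagen genes went both ways. Of 73 moulting and larval epidermis genes, 40 were lower, 2 were higher and 31 did not pass, with a median of -0.53 (camera adjusted p = 6.2e-08, and adjusted p = 0.243 with an estimated correlation); the counts were the same adjusted over the list alone. The ground-like genes grl-7 and grl-20 stood at -3.01 ± 0.37 and -2.85 ± 0.40. Of 151 cuticle collagen genes, 34 were higher, 75 were lower and 42 did not pass, with a range from -4.75 (col-36) to 3.49 (col-101) and a median of -0.46; adjusted over the list alone, 38 were higher and 76 lower. The collagen gene col-2 stood at -4.06 ± 0.22. The list lay lower than other genes by camera (adjusted p = 0.00123), with an adjusted p = 0.570 with an estimated correlation. Of 28 pharynx structural genes, 16 were lower, 1 was higher and 11 did not pass, with a median of -0.50 (camera adjusted p = 0.00148, and adjusted p = 0.243 with an estimated correlation); over the list alone, 17 were lower and 1 higher. The gland protein gene phat-5 was 7.98-fold lower, and phat-8 stood at -1.63 ± 0.17.

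Neuron genes were lower as a group. Of 62 measured, 44 were lower and 18 did not pass, with a median of -0.81, or 1.76-fold lower; adjusted over the list alone, 48 were lower and 2 higher. The neuropeptide gene flp-1 stood at -3.63 ± 0.33, 12.4-fold lower, and the dense core vesicle gene ida-1 at -2.83 ± 0.22. The camera adjusted p was 3.99e-11, with an adjusted p = 0.243 with an estimated correlation. Muscle genes went both ways: of 36, 9 were higher, 9 were lower and 18 did not pass (11 higher and 9 lower over the list alone; camera adjusted p = 0.837). The troponin genes tnc-2 and tni-1 stood at -2.65 ± 0.22 and -1.02 ± 0.10.

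The 3 measured yolk protein genes, whose products are made in the adult hermaphrodite intestine, were not called as a group. The vit-2 gene was 2.05-fold higher, at 1.03 ± 0.63 (adjusted p = 0.00776), with 1.73, 0.48 and 0.90 on replicates 1 to 3. The vit-5 and vit-6 genes did not pass, at -0.06 ± 0.39 and 0.06 ± 0.24, and the list had a camera adjusted p of 0.557. Adjusted over the list alone, 1 gene was higher. Of 45 other intestine genes, 14 were higher, 22 were lower and 9 did not pass (15 higher and 23 lower over the list alone; camera adjusted p = 0.264), ranging from acs-2 at -4.96 to acdh-1 at 3.08, with the protease gene cpr-2 at -3.37 ± 0.72. Of 254 genes of lysozymes, lectins and antimicrobial peptides, 20 were higher, 57 were lower and 177 did not pass (14 higher and 54 lower over the list alone; camera adjusted p = 0.202). Beside clec-60, the lysozyme gene lys-3 stood at -2.79 ± 0.74. Of 34 heat shock and oxidative stress genes, 11 were higher, 10 were lower and 13 did not pass (12 higher and 10 lower over the list alone; camera adjusted p = 0.597), with hsp-12.3 at -2.62 ± 0.37. Their median was 0.05, their mean was -0.09, and camera put the list on the higher side.

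None of the 5 remaining lists was called by camera. Each held genes past the threshold, which 44.4% of all tested genes passed. Early embryo genes had 15 higher, 5 lower and 34 not passing of 54 (14 and 5 over the list alone; adjusted p = 0.0874), with sdz-6 at 1.35 ± 0.35 and sdz-24 at -2.73 ± 0.78. Mitochondrial respiration genes had 10 higher and 9 lower of 43, over all genes and over the list alone (adjusted p = 0.557), with sdha-2 at 1.40 ± 0.11 and ucr-2.3 at 1.38 ± 0.21. Genes of the gonad sheath, spermatheca, uterus and vulva had 4 higher and 6 lower of 24, over all genes and the list alone (adjusted p = 0.632), with egl-15 at -1.26 ± 0.12 and let-502 at 1.18 ± 0.25. Of 13 male-enriched genes, 2 were lower by both adjustments and 11 did not pass (adjusted p = 0.632), namely swm-1 at -1.46 ± 0.28 and cwp-4 at -0.61 ± 0.17. Of 10 heterochronic genes, which time larval stages, 2 were higher and 3 lower by both adjustments (adjusted p = 0.827), with nhl-2 at 0.81 ± 0.27 and lin-29 at -0.66 ± 0.21. The lin-29 call did not hold without replicate 3 (adjusted p = 0.0526).

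**Figure D2:**
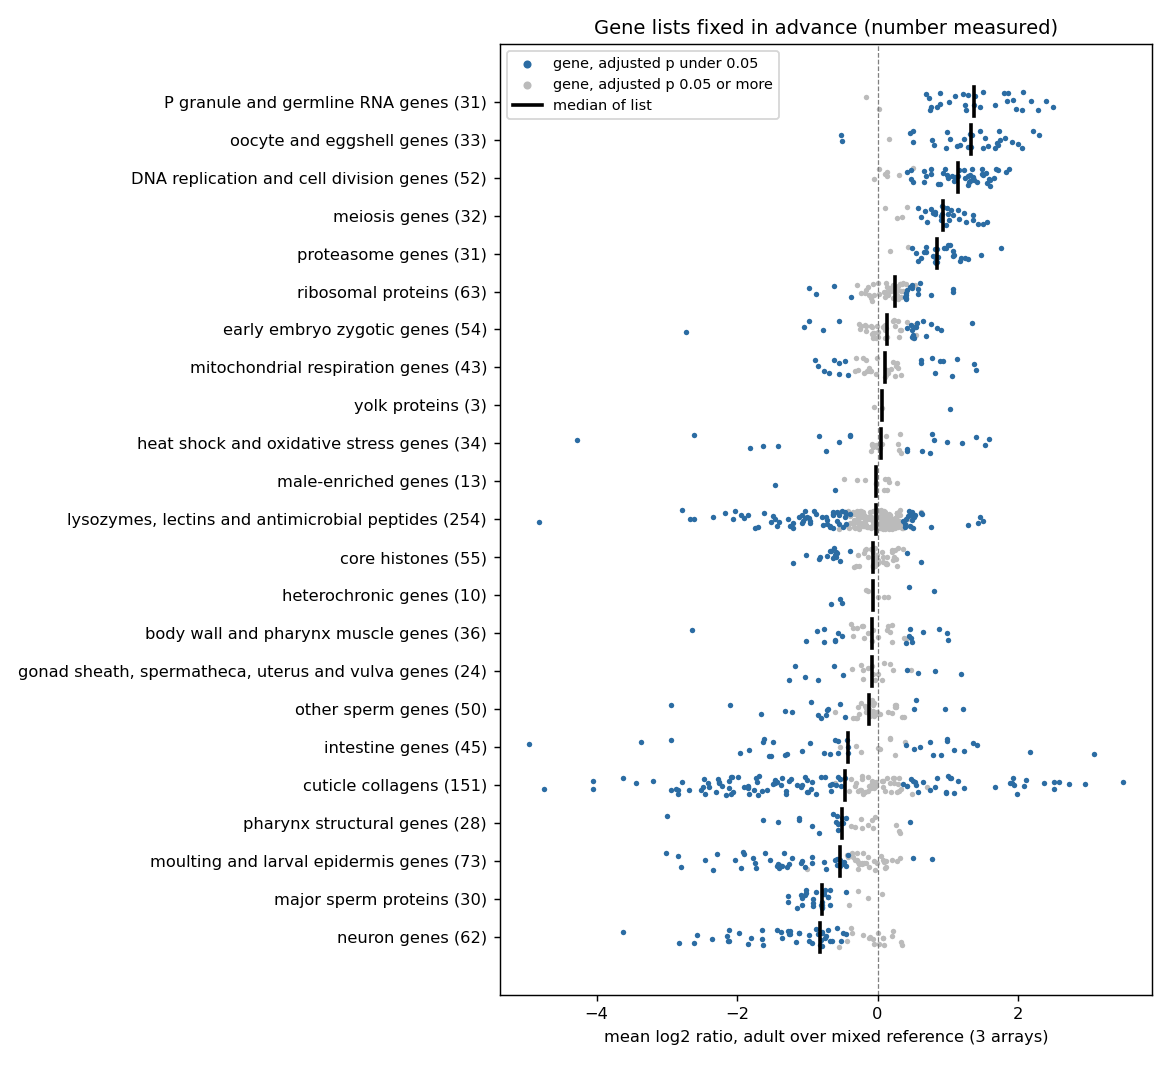
Mean log2 ratio (adult over mixed reference, 3 arrays) of each measured member of the 23 gene lists; each point is a gene, blue where its adjusted p is under 0.05 and grey otherwise, and the black bar is the list's median. The oocyte, P granule, meiosis, cell division and proteasome lists lie above 0 with medians of 0.84 to 1.37. The neuron and major sperm protein lists lie below 0 with medians of -0.81 and -0.79, and collagens spread from -4.75 to 3.49.

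The 3 arrays ranked the genes alike, but replicate 1 stood apart. Across genes, which are not independent replicates, Pearson's r was 0.82 for replicates 1 and 2, 0.85 for replicates 1 and 3, and 0.92 for replicates 2 and 3, and Spearman's rho was 0.75, 0.78 and 0.88. No array correlated negatively with another. The deviation of replicate 1 from the mean of the other arrays followed the order of the probes in the table. Over 32 equal runs of consecutive rows, its median cycled with every 4 runs, from a mean of 0.24 in the first position to -0.24 in the fourth, each over 8 runs. The runs accounted for 20.2% of the variance of that deviation. Without replicate 1, 7097 genes passed the test against 6698 with all arrays, and 6281 genes passed in both with the same sign.

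**Figure D3:**
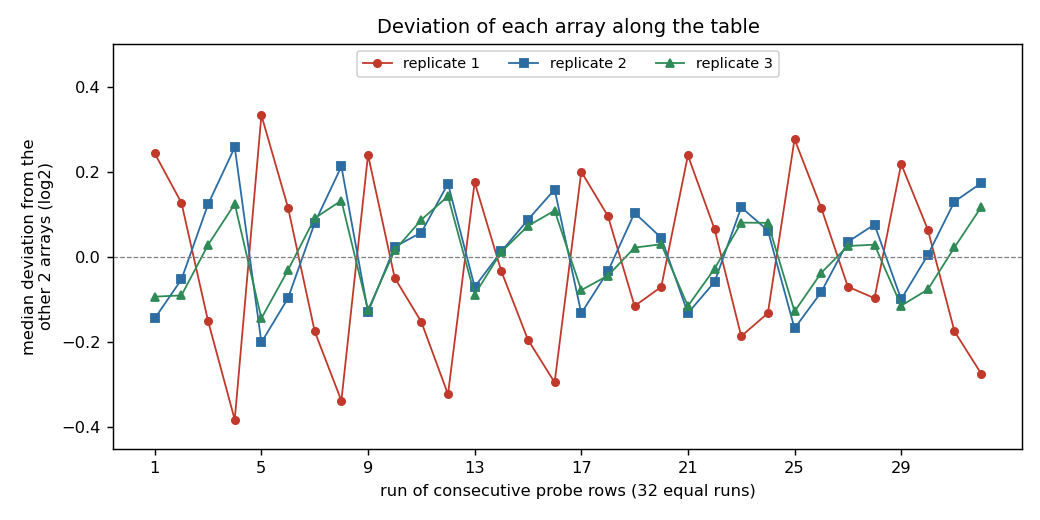
Median deviation (log2) of each array from the mean of the other 2 arrays, in 32 equal runs of consecutive probe rows; each point is 1 run and the dashed line marks 0. Replicate 1 swings with every 4 runs by an amount that varies, with extremes of 0.33 and -0.38 in single runs. Replicates 2 and 3, each measured against a mean that includes replicate 1, swing the other way.

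By camera with the preset correlation, 11 of the 23 lists were called. With an estimated correlation, which rests on 2 residual degrees of freedom, camera called 0 of 23 (lowest adjusted p = 0.243), and 3 had an unadjusted p under 0.05. By fry, which tests whether a list's genes move one way and does not compare them with other genes, 12 lists were called.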

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

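The number of genes that differed stayed within 1.5 times the 6698 reported under all alternatives except treat against a 1.5-fold change, which asks for a larger effect and called 2076 genes (912 higher and 1164 lower). Leaving out 1 replicate gave 4954 to 7097 genes, the fewest without replicate 3, and array weights, which gave replicate 1 a weight of 0.37, gave 8309. Centring by 32 runs, by 4 positions and testing unnamed probes too, all chosen after seeing the data, gave 6855, 6971 and 8050. With centring by 32 runs, 5999 of the 6698 genes kept their call and sign. With genes past the threshold left out, r fell to 0.049, 0.148 and 0.437 for replicates 1 and 2, 1 and 3, and 2 and 3, as that choice removes the genes that differ. With an estimated correlation camera called 0 lists (3 at an unadjusted p under 0.05): the adjusted p was 0.243 for the oocyte, meiosis, P granule, cell division, moulting, pharynx, neuron and proteasome lists, 0.613 for major sperm proteins, 0.737 for ribosomal proteins and 0.570 for collagens. By fry, major sperm proteins (0.0766) and ribosomal proteins (0.167) were not called, while intestine (0.0300), lysozyme and lectin (0.0490) and male-enriched genes (0.0472) were, and the uncalled heat shock list changed sides (0.247); the cause was not tested. Other settings changed no list call, except that leaving out 1 replicate gave 0.0399 to 0.233 for other sperm genes and 0.575 to 0.692 for muscle genes, which changed sides without replicate 2. Testing against 1.5-fold ended the calls of 4 of the 63 named genes (vit-2, cwp-4, nhl-2 and lin-29). Among named genes, the uncalled vit-5 changed sign with array weights (0.17) and ranged from -0.28 to 0.085 without 1 replicate, and the uncalled vit-6 changed sign with centring by 32 runs (-0.072) and ranged from -0.060 to 0.18. No paired analysis was possible because there is only 1 group. Signal over background was not used here, so how far the noise of dim spots enters the ratios was not assessed.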

Other observations

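The tests in this part were chosen after the main results were seen, and those of position in replicate 1, of the fasting list by camera and of the spread of its difference from the moulting list were set after the values they bear on were seen. Genes singled out here were also chosen after their values were seen. Genes that share a name prefix, with at least 8 measured members, were tested as groups in the same way as the lists. Some prefixes stand for a mutant phenotype and not for a family, such as him and let among those higher and unc among those lower; 8 of the neuropeptide-like and 3 of the nuclear hormone receptor genes are also members of the report's lists. Of 188 such groups, 21 lay higher and 29 lower by camera with the preset correlation, and with an estimated correlation camera called 0 (lowest adjusted p = 0.645), with 6 at an unadjusted p under 0.05. The median of each group named in this paragraph kept its sign in the values as deposited and under scale and quantile normalization. The values as deposited differ from the centred ones only by a constant on each array, so a kept sign there is no separate support for a group. Of 21 nuclear pore genes (npp), 20 were higher, with a median of 1.22 (adjusted p = 3.44e-09). Higher too were 10 of 11 pre-mRNA processing genes (prp, median 0.86, adjusted p = 0.000422) and 11 of 19 translation initiation factor genes (eif, median 0.68, adjusted p = 0.00119). Lower were 37 of 52 neuropeptide-like genes (nlp, median -1.02, adjusted p = 2.77e-10), 30 of 46 transthyretin-like genes (ttr, median -0.80, adjusted p = 8.79e-07), 88 of 237 nuclear hormone receptor genes (nhr, median -0.25, adjusted p = 0.000422), 15 of 25 globin genes (glb, median -0.49, adjusted p = 0.00183) and 12 of 22 insulin-related genes (ins, median -0.45, adjusted p = 0.00803).

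Within the heat shock list, hsp-110 at 1.59, hsp-1 at 1.53, hsp-4 at 1.20 and hsp-90 at 1.00 were among the higher members, and hsp-12.6 at -4.29, hsp-12.3 at -2.62, hsp-70 at -1.82 and hsp-16.20 at -1.42 among the lower, while hsp-16.48 at 0.33 did not pass. Some genes with near-identical names went opposite ways: rpl-11.1 stood at 1.07 and rpl-11.2 at -0.88, a difference of 1.95 ± 0.25 (SD, n = 3); rpl-23A.1 lay below rpl-23A.2, with a difference of -2.04 ± 0.09; and ucr-2.1 lay below ucr-2.3, with a difference of -2.27 ± 0.19. Opposite calls were not the general pattern among such genes. Among 253 pairs that share a name up to the last point, 17 were called in opposite directions. The mean was 25.5 in 10000 reshufflings of the 235 genes. In the same direction 47 pairs were called, against a mean of 26.6. Similar copies can share signal, which favours calls in the same direction, so these counts do not show how often such genes differ.

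Of the probes with no gene symbol, 3987 were tested, of which 776 were higher and 567 lower. Of 194 probes with several symbols, 72 were higher and 34 lower. The unnamed probe 2716383 stood at 5.47 ± 1.04 (SD, n = 3), above the highest named gene, and probe 2698877 at 4.78 ± 0.16. The lowest unnamed probe, 2711959, stood at -3.72 ± 0.43.

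Replicate 1 differed from the other arrays in a pattern that follows the table's row order. The mean of its run medians was 0.24, 0.06, -0.15 and -0.24 at the 4 repeating positions, and position accounted for 87.3% of the variance of the 32 medians, a share that describes the cycle and does not test it, since the positions were read from these medians. The fixed gene lists accounted for 2.84% of the variance of its deviation over 1207 listed genes, against 20.2% for the runs over all probes. Differences between these lists were thus a small part of it. Noise of single genes lowers both shares, and differences within a list or outside the lists do not enter. The share therefore does not decide against a difference in tissue or stage between preps. A candidate explanation, drawn from these values and left open by them, is a gradient across the slide, with the runs as printed blocks. Centring the runs raised r with replicates 2 and 3 from 0.82 to 0.84 and from 0.85 to 0.87, still below the 0.92 between replicates 2 and 3, so what remains of the difference is open, including effects of position within a run and of the prep.

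Several of the lowest genes, such as acs-2 and hsp-12.6, are used in fasting or in the dauer larva, an arrested larval form. A list of 16 other genes of these states, of which 14 were measured and 4 are also in the fixed lists, had a median of -1.28, lower than all 10000 random lists of that size (a percentile of 0.01, the smallest they can give); it was -1.12 without hsp-12.3, which the report names, and again lower than all 10000. Of the 14, 10 were lower, among them icl-1 at -2.48, hacd-1 at -1.97 and mtl-1 at -2.94, while lbp-8 was higher at 1.31 and sod-3 did not pass at 0.04. Other groups lay nearly as low, such as the flp neuropeptide genes (median -1.27, 22 genes) and the nlp genes (median -1.02, 52 genes). A median this far below random lists was thus not particular to genes of fasting or dauer. Random lists take genes as independent. By camera the fasting list's unadjusted p was 0.000159 with the preset correlation and 0.0778 with an estimated one, which was 0.032. The test with an estimated correlation rests on 2 residual degrees of freedom, so these p-values do not show whether the shift depends on independence of genes. As a hypothesis, the mixed reference may have held fasting or dauer larvae, while a lower level of these genes in the adults gives the same ratio and larval epidermis in the reference stays open too (difference of -0.75 from the median of the moulting list on the log2 scale, 95% bootstrap interval -1.56 to 0.42 over genes, two-sided permutation p = 0.0599).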
